A study of Homo sapiens with 54 samples.

How the data were processed

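The authors deposited raw counts per gene for both platforms, 63677 gene rows for Illumina and 51058 for Ion Torrent, and no other unit was used. Per the labels, cells were sorted to over 95% purity, their RNA was amplified with SMARTer in 12 to 16 PCR rounds, and libraries were read as Illumina pairs or on Ion Torrent. Tissue was digested with an enzyme at 37 C for 20 min, while blood was enriched for CD4 cells without digestion. Also per the labels, reads were trimmed with Trimmomatic 0.32, aligned to GRCh38 with TopHat2 2.0.11 and Bowtie2 2.2.2, handled with SAMtools 0.1.19 and counted with HTSeq 0.6.1p1. The annotation release, strand setting and read filters were not stated.

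Libraries were grouped by the platform, tissue, cell type and surface marker in their labels, and replicates were named by the number in the label, which the labels give to donors. The grouping, the 14 comparisons, the gene lists, the rule for naming genes, the tests of genes and lists and most alternatives were fixed before the data were examined. Chosen after the data were seen were the epithelial marker score as a covariate, leaving out libraries with a high epithelial score or with few detected genes, list members by labels sorted again, list tests with a block, and the replicate block for the Ion Torrent interaction. Also chosen then were the tests of label order, noisy counts, the breast calls on both platforms, the CD177 call, the sparse library, epithelial RNA and tissue digestion.

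Group medians of gene counts, in M, were 14.5 for tumor Treg, 12.2 for breast Treg, 13.4 for tumor Tconv, 12.1 for breast Tconv, 14.7 for CD177 positive and 12.7 for CD177 negative tumor Treg on Illumina. On Ion Torrent they were 10.7 for tumor Treg, 12.8 for tumor Tconv, 9.93 and 8.41 for CD45RO and CD45RA blood Treg, and 9.95 and 8.56 for CD45RO and CD45RA blood Tconv. Illumina libraries had 15928 to 33795 detected genes and Ion Torrent libraries 19027 to 27953. Reads outside any gene feature were 8.22 to 32.5% on Illumina and 59.5 to 71.1% on Ion Torrent.

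Symbols and coordinates were taken from GENCODE 29 on GRCh38, which matched 40044 Illumina and 28982 Ion Torrent rows. Of the Ion Torrent rows, 20609 would carry another label if names were sorted in another order, and these hold 19.6% of gene counts. Only the 30449 rows with the same label under both orders were named or entered in lists, which is why CD4 is not given for Ion Torrent, but all rows entered the fit. A further 27 names in that table had been turned into dates. Left out of all tests by a fixed rule were 1200 Illumina and 416 Ion Torrent rows. Immunoglobulin and T cell receptor segments, genes with common whole-gene deletions and symbols that are only clone names were not named.

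Each table was fitted alone in edgeR 4.0.16 (R 4.3.3), with all its groups in a single model without a block. Genes passed filterByExpr (24752 on Illumina, 18948 on Ion Torrent), libraries were scaled by TMM (factors 0.533 to 1.49 and 0.758 to 1.21), and glmQLFit with robust estimation and 2-sided glmQLFTest gave p-values adjusted by Benjamini and Hochberg within each comparison. The common dispersion was 0.833 with 28 residual degrees of freedom on Illumina and 0.193 with 14 on Ion Torrent. Means are CPM on TMM effective library sizes. Genes were named if they had an adjusted p under 0.05, a log2 fold change of at least 1 in size and 10 CPM in the higher group, taking 10 per direction by p for the 6 main comparisons and 5 for the others. FOXP3, IL2RA, IL7R, CD4, CD177 and CCR8 were named always, and up to 4 members per described list. For a group without counts the fold is a lower bound at a floor of 3 counts, and for 1 to 3 counts the ratio carries a 0.95 counting interval.

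Gene lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01 and again with the correlation estimated from the data, adjusted over the lists of a comparison. Of all list tests 175 passed with the preset and 63 with the estimated correlation. Fry, which does not compare a list with other genes, passed 101. Marker scores are mean log2 CPM with a prior count of 3, and correlations with scores were tested with 100000 permutations.

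Alternatives were DESeq2 size factors in edgeR, scaling by total counts, the DESeq2 1.42.0 Wald test, limma voom with a random replicate block, no filter, a stricter filter, only the groups compared, CD177 fractions as tumor Treg, leaving out each library, and a fixed replicate block. Total counts moved the median log2 fold change of all genes by -0.15 in tumor against breast Tconv, 0.12 in the Illumina interaction, -0.19 in breast Treg against Tconv, 0.26 in tumor against blood Treg, 0.25 in tumor against blood Tconv and -0.11 in blood CD45RO against CD45RA Tconv. DESeq2 size factors moved it by at most -0.09, in tumor against breast Treg. Group labels of the same libraries were also split in other ways and the called genes counted again.

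Residuals within groups were correlated between libraries of the same number. On Illumina 48 such pairs had a median r of 0.148, with 25 over 0.1, and 424 other pairs had -0.03. On Ion Torrent 17 pairs had a median of 0.440, with 16 over 0.1, and 146 other pairs had -0.05. No libraries were identical. Some genes that met the rule for naming are not reported here.

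The procedure was tested on simulated data with 200 changed genes. It recovered 0, 13.4 and 25.8% of genes changed by 2, 4 and 8-fold in the design of tumor against breast Treg, with 1 false call among 27, and 5.97, 55.2 and 65.2% in that of tumor against blood Treg, with 5 among 89. For Treg against Tconv in the tumor it recovered 1.49, 17.9 and 34.8% on Illumina and 5.97, 49.3 and 68.2% on Ion Torrent. Simulated counts were drawn independently for each library, without correlation within replicate numbers, sparse libraries or RNA of other cells. The shares of recovered genes and false calls may therefore not carry over to the real libraries. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.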

Results

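Gene expression was compared between regulatory T cells (Treg, sorted as CD25 high and CD127 negative CD4 T cells) and conventional CD4 T cells (Tconv, CD25 negative) of breast tumors, normal breast parenchyma and blood. The deposited tables hold raw counts of 54 libraries from 19 replicate numbers, which the labels give to donors. On Illumina, 34 libraries of 10 numbers cover tumor Treg (n = 3), breast Treg (n = 6), tumor Tconv (n = 9) and breast Tconv (n = 6), with tumor Treg sorted further into CD177 positive (n = 5) and CD177 negative (n = 5) cells. On Ion Torrent, 20 libraries of 9 numbers cover tumor Treg (n = 3), tumor Tconv (n = 5), blood Treg that were CD45RO positive, an activated state (n = 4), or CD45RA positive, a resting state (n = 4), and blood Tconv of either state (n = 2 each). Gene counts per library ran from 8.18 M to 17.3 M on Illumina (median 13.2 M) and from 5.20 M to 14.9 M on Ion Torrent (median 9.52 M), so 1 CPM rests on about 5 to 17 counts in a library. Levels are CPM with the SD over libraries, and adjusted p-values of genes come from edgeR unless another tool is named. Log2 fold changes carry an SE computed as their size over the square root of the quasi-likelihood F statistic. This SE therefore restates the test and is no separate measure of spread. Counting intervals and floors cover counting error only, since PCR copies were not told apart by molecular identifiers. Each table was analysed alone.

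Treg were first compared with Tconv in the tumor on Illumina (n = 3 and 9), in a fit without a block. Each tumor Treg library shares its replicate number with a tumor Tconv library. CCR8, a chemokine receptor, averaged 546 ± 118 CPM in tumor Treg (range 415 to 644) and 15.9 ± 6.07 CPM in tumor Tconv (range 10.5 to 30.2), 34.4-fold higher (log2 fold change 5.11 ± 0.54, adjusted p = 8.17e-07; GRCh38 chromosome 3, 39329706 to 39333511). FOXP3, the transcription factor that directs the Treg program, rose 37.5-fold from 6.87 ± 5.91 to 257 ± 110 CPM (log2 fold change 5.23 ± 0.63, adjusted p = 7.42e-06; chromosome X, 49250436 to 49264826). IL2RA, which encodes the CD25 of the sort, rose 23.9-fold from 31.3 ± 9.95 to 746 ± 119 CPM (log2 fold change 4.58 ± 0.49, adjusted p = 8.17e-07; chromosome 10, 6010689 to 6062370). CD177, a surface glycoprotein known from neutrophils, rose 453-fold, from 0.0659 ± 0.102 to 36.8 ± 30.3 CPM with a range of 1.85 to 56.6 among tumor Treg (log2 fold change 8.82 ± 1.00, adjusted p = 2.48e-06; chromosome 19, 43353659 to 43363172). Among receptors, TNFRSF9, a costimulatory receptor, rose 39.0-fold to 566 ± 225 CPM and IL1R2, a decoy receptor of interleukin 1, rose 89.9-fold to 250.1 ± 166 CPM. STAM (8.60-fold), FANK1 (35.1-fold) and the long noncoding RNA LINC02099 (17.6-fold) rose as well. The pseudogene HNRNPA1P21, 57.3-fold higher, lies next to CCR8, so its signal is uncertain.

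Of the genes that fell in tumor Treg on Illumina, ANXA1, a phospholipid-binding protein, dropped 26.5-fold from 1483 ± 315 to 55.9 ± 53.3 CPM (n = 9 and 3; log2 fold change -4.73 ± 0.84, adjusted p = 0.00214; chromosome 9, 73151757 to 73170393). GZMK, a granzyme of cytotoxic lymphocytes, fell 107-fold from 121 ± 51.9 to 1.11 ± 1.53 CPM (adjusted p = 0.00787), and TCF7, a transcription factor of naive and memory T cells, fell from 273 ± 109 to 19.5 ± 7.33 CPM (log2 fold change -3.81 ± 0.76, adjusted p = 0.00821). C1orf162, PLAC8, MGAT4A, LINC01871, HOPX and ACSL6 fell by 8.66-fold (ACSL6) or more. IL7R, the receptor behind the CD127 of the sort, averaged 790.4 ± 333 against 3194 ± 878 CPM (log2 fold change -2.01 ± 0.53, adjusted p = 0.0757; chromosome 5, 35852695 to 35879603). CD4 had a log2 fold change of 0.64 ± 0.48 (adjusted p = 0.718; chromosome 12, 6786858 to 6820808). In all, 123 of 24752 tested genes rose and 25 fell (edgeR, adjusted p under 0.05; 2250 had a raw p under 0.05 and 1238 were expected by chance). The balance turned in DESeq2, with 197 that rose and 319 that fell, and with CD177 fractions as tumor Treg, with 548 and 663. Fits without tumor Treg replicate 1, 5 or 8 gave 72, 70 and 91 genes. C1orf162, TCF7 and MGAT4A lost their call without tumor Treg replicate 1 or 5, PLAC8 without 5 or 8, GZMK without 1 or 8, and LINC01871, HOPX and ACSL6 without any of the 3. With the replicate number as a block, 71 genes passed, and IL1R2, LINC01871 and ACSL6 did not (adjusted p = 0.0875, 0.137 and 0.169).

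The gene lists place these genes in wider programs of tumor Treg against tumor Tconv on Illumina. Of 15 Treg identity genes, 10 rose and 14 passed when adjusted over the list alone, with STAM, IL2RA and FOXP3 ahead and IKZF2, a transcription factor of stable Treg, at 419.8 against 23.2 CPM. Of 15 genes reported for Treg of other tumors, 11 rose and all 15 passed when adjusted over the list alone. They include VDR, the vitamin D receptor, with a log2 fold change of 4.18 ± 0.65 (adjusted p = 3.70e-04, and 0.0526 with the replicate block). Among 16 TNF receptor superfamily genes, 4 rose and 9 passed when adjusted over the list alone, led by TNFRSF13B, TNFRSF9, TNFRSF1B and FAS. TNFRSF13B had 2 counts over all tumor Tconv, a ratio of 586 with a counting interval of 161 to 4856. Of 14 immune checkpoint genes, HAVCR2, TIGIT, ICOS and CTLA4 rose by log2 fold changes of 2.57 ± 0.51, 2.94 ± 0.60, 2.19 ± 0.51 and 2.88 ± 0.68 and 1 fell. With the replicate block ICOS and CTLA4 had an adjusted p = 0.125 and 0.0804. None of 12 genes known to be low in Treg passed over all genes, and 8 fell when adjusted over the list alone, led by IL7R, CD40LG and THEMIS. Of 20 proliferation genes none passed, also when adjusted over the list alone, but all 20 were higher, with a median log2 fold change of 1.58 and CCNB1 at 54.2 against 13.2 CPM. Of 13 naive and lymph-node homing genes, TCF7 alone fell, and the list had a median of -1.20. The checkpoint list passed camera (median 0.76, adjusted p = 5.10e-04) but had an adjusted p = 0.145 with an estimated correlation (0.0229 without libraries of high epithelial score). The lists of identity, other tumors, TNF receptors, genes low in Treg, proliferation and naive genes passed under both correlations, with adjusted p = 1.53e-05, 9.32e-07, 0.00253, 3.27e-04, 0.0188 and 0.0188 under the estimated one.

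Markers of other cell types and of library quality also differed between tumor Treg and tumor Tconv on Illumina. In tumor Treg 26.5 to 27.4% of reads were not aligned uniquely, against 31.5 to 37.2% in tumor Tconv. CD177 negative and positive tumor Treg had 30.2 to 35.5% and 29.7 to 34.1%, so the low share is not one of all tumor Treg. All 13 mitochondrially encoded genes were lower in the tumor Treg not sorted on CD177 than in tumor Tconv, with a median of -1.05 (camera adjusted p = 3.52e-07; adjusted p = 0.199 with an estimated correlation). Of 12 CD8 T and NK cell markers none passed over all genes and 4 fell when adjusted over the list alone, with EOMES, a transcription factor of cytotoxic cells, at 0.417 against 45.8 CPM and GZMH at 1.84 against 48.8 CPM. The list median was -2.44, or -2.23 with genes absent from a group set at their bound (camera adjusted p = 0.00140; adjusted p = 0.110 with an estimated correlation). Of 11 B and plasma cell markers, CD79A (log2 fold change 5.10 ± 1.10) and MZB1 (3.09 ± 0.69) rose (adjusted p = 0.0153 and 0.0206, and 0.265 and 0.876 with the replicate block), while the median of the list was -1.02 and its camera direction was up (adjusted p = 0.203). All 16 epithelial markers were lower in tumor Treg, none past the threshold, with a median of -2.69 and CLDN4 at 0.899 against 30.0 CPM (camera adjusted p = 0.00414; adjusted p = 0.489 with an estimated correlation; 0.0576 with the replicate block). All 15 monocyte, macrophage and dendritic cell markers were lower, none past the threshold, with C1QA at 0.681 against 9.31 CPM (camera adjusted p = 2.40e-05; adjusted p = 0.202 with an estimated correlation).

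**Figure D1:**
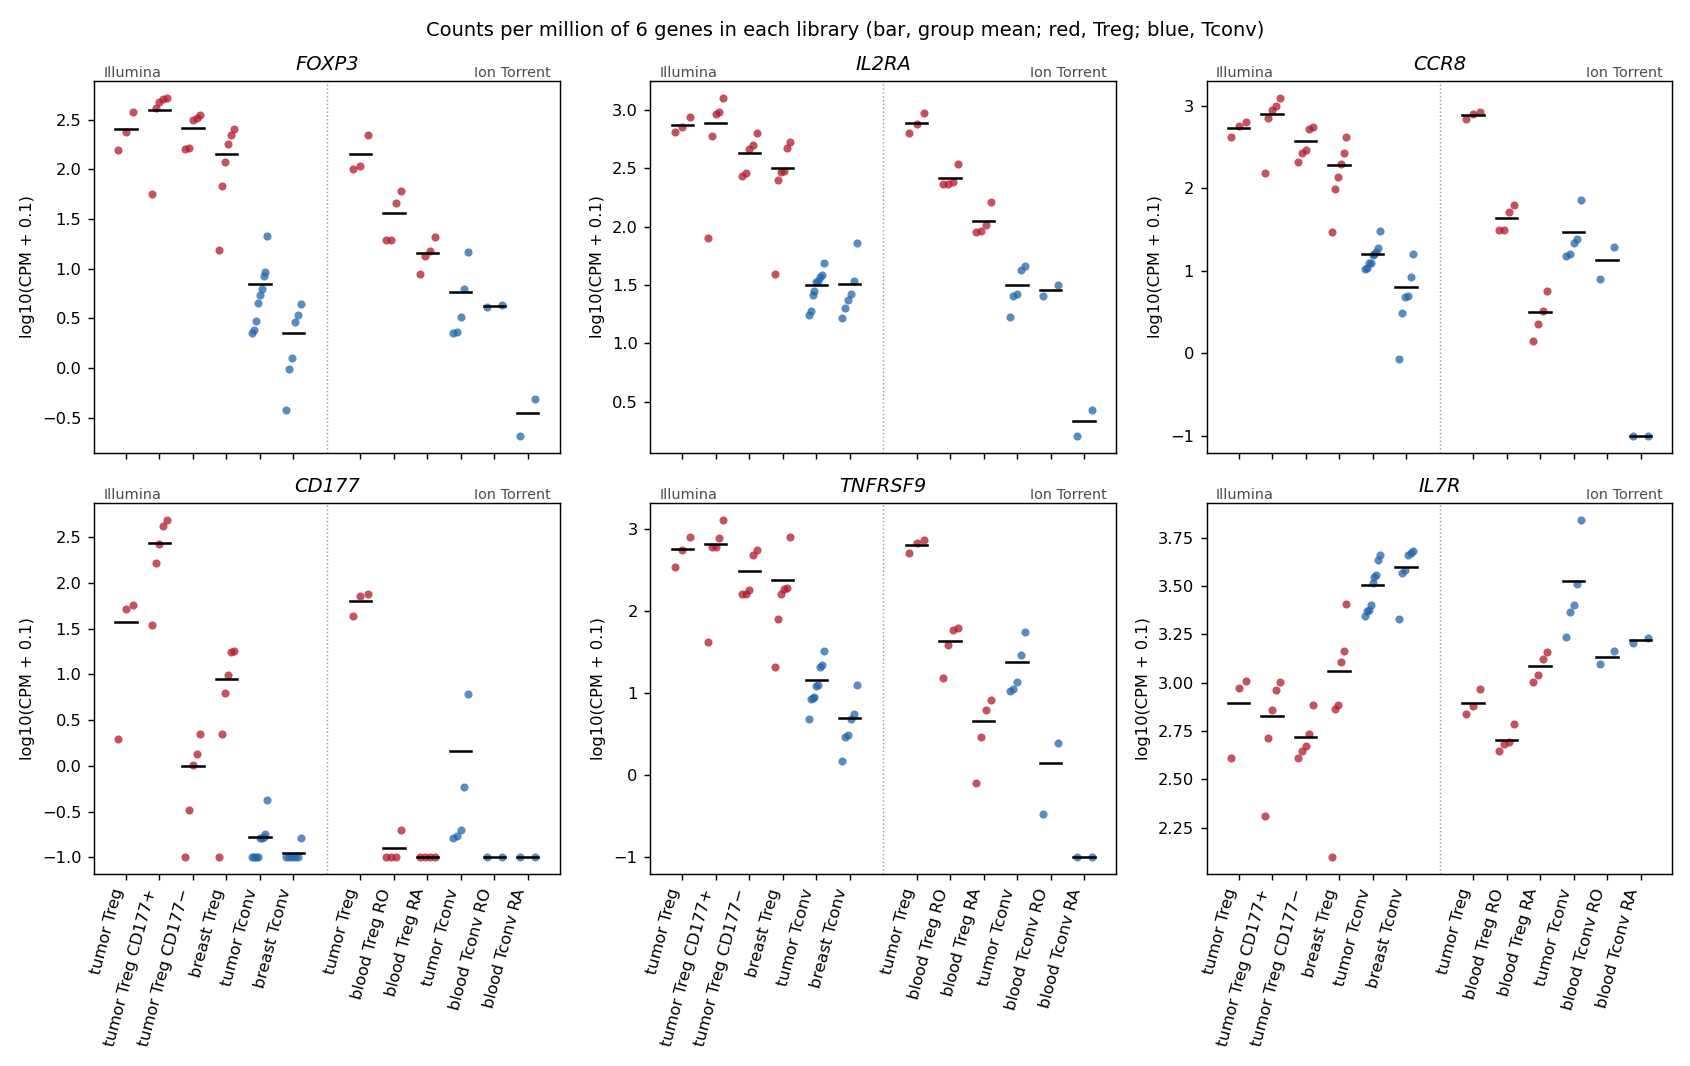
Levels of FOXP3, IL2RA, CCR8, CD177, TNFRSF9 and IL7R in each library, as log10 of CPM plus 0.1, by sorted group on Illumina (left of each panel, 34 libraries) and Ion Torrent (right, 20 libraries). Bars are group means, and CCR8 averaged 546 CPM in tumor Treg and 15.9 CPM in tumor Tconv on Illumina.

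The same question was asked of other tumors on Ion Torrent (tumor Treg n = 3, tumor Tconv n = 5), again without a block. Here too each tumor Treg library shares its replicate number with a tumor Tconv library. IL2RA rose 24.8-fold from 31.4 ± 12.3 to 776 ± 152 CPM (log2 fold change 4.63 ± 0.31, adjusted p = 2.18e-08), CCR8 rose 26.4-fold from 29.7 ± 24.0 to 779 ± 73.0 CPM (adjusted p = 1.11e-05) and FOXP3 rose 26.1-fold from 5.67 ± 5.30 to 143 ± 66.6 CPM (adjusted p = 2.96e-05). IKZF2 rose 13.2-fold to 555 ± 59.8 CPM and TIGIT, an inhibitory receptor, 5.15-fold to 1119 ± 112 CPM. ACSL4, CDCA7L, ADTRP, INPP5F and PARPBP were 4.23-fold (ACSL4) to 8.82-fold (CDCA7L) higher. CD177 averaged 63.0 ± 17.5 against 1.36 ± 2.64 CPM, with a log2 fold change of 5.78 ± 1.04 (adjusted p = 0.00383, not past the threshold in DESeq2) that became 8.33 ± 0.63 without tumor Tconv replicate 14. GZMA, a granzyme, fell 32.8-fold from 145 ± 49.1 to 4.43 ± 1.03 CPM (log2 fold change -5.04 ± 0.40, adjusted p = 1.76e-07). MPP7, PLAC8, TC2N, GIMAP7, TCF7, TMEM71, MAN1C1, PLXDC1 and ACSL6 fell by 7.38-fold (GIMAP7) to 39.8-fold (PLAC8). IL7R fell 4.26-fold from 3362 ± 2089 to 790.0 ± 123 CPM (adjusted p = 9.03e-04). Altogether 489 of 18948 genes rose and 477 fell (edgeR; 2983 at a raw p under 0.05, 947 expected). Fits without tumor Treg replicate 14, 15 or 16 gave 530, 529 and 630 genes, each still with all genes named by the rule.

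In those tumors on Ion Torrent, 8 of 12 Treg identity genes rose in tumor Treg and 11 passed when adjusted over the list alone. Of 14 genes reported for Treg of other tumors 9 rose, 12 when adjusted over the list alone, with IL1R2 at 107 against 1.67 CPM and LAYN at 54.6 against 2.50 CPM. TIGIT, HAVCR2 and ICOS rose among 9 checkpoint genes, and TNFRSF9, TNFRSF1B, TNFRSF8 and TNFRSF4 led 7 of 14 TNF receptors that rose. Of 10 naive and lymph-node homing genes 7 fell, while 8 fell and 1 rose when adjusted over the list alone; the fallen include CCR7, which guides T cells to lymph nodes, with a log2 fold change of -2.60 ± 0.34. Of 7 genes low in Treg 4 fell, with ANK3 at 4.11 against 142 CPM. Of 12 CD8 T and NK cell markers 4 fell, 6 when adjusted over the list alone, with EOMES at 0.204 against 40.5 CPM and a list median of -2.62 (-2.38 at bounds). These 7 lists passed camera under both correlations, with estimated-correlation adjusted p = 2.66e-05, 2.66e-05, 0.00350, 0.00472, 2.74e-04, 2.74e-04 and 0.0217 in the order above. For the TNF receptors the estimated-correlation value with the replicate block was 0.103. Of 19 proliferation genes 3 rose and 15 passed when adjusted over the list alone, but the list had an adjusted p = 0.0896 with an estimated correlation (camera adjusted p = 5.05e-10).

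Across the 10217 genes with a certain name that were tested on both platforms, 84 had risen in tumor Treg on Illumina and 344 on Ion Torrent, and 66 had risen on both where 2.83 were expected by chance. Of 17 genes that fell on Illumina 15 fell on Ion Torrent (0.468 expected). Among the 84 risen genes 83 had the same sign on Ion Torrent, as did all 17 fallen genes, and no gene was called in opposite directions. The log2 fold changes of all 10217 genes correlated at r = 0.559.

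**Figure D2:**
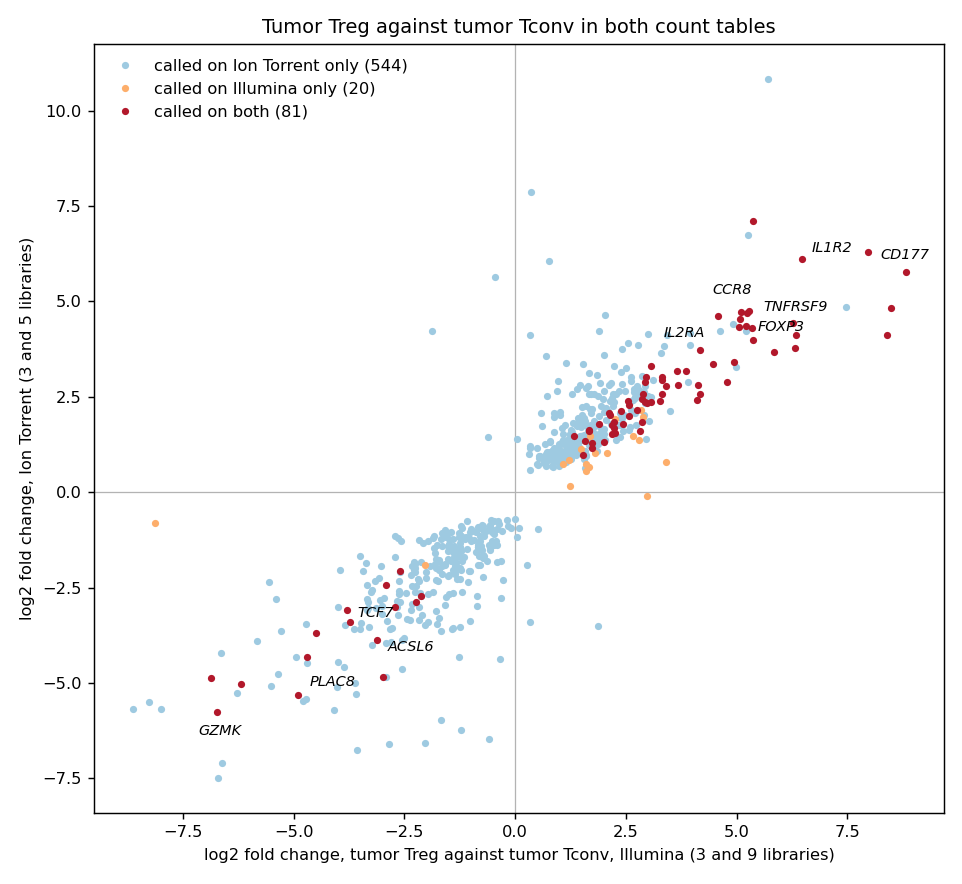
Log2 fold change of tumor Treg against tumor Tconv on Illumina (horizontal, 3 and 9 libraries) and Ion Torrent (vertical, 3 and 5 libraries) for genes called on either. Points mark 81 genes called on both, 20 called on Illumina alone and 544 called on Ion Torrent alone.

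In normal breast parenchyma, Treg were compared with Tconv of the same replicate numbers on Illumina (n = 6 each), in a fit without a block. CCR8 rose 30.9-fold, from 6.20 ± 5.27 CPM in breast Tconv (range 0.746 to 15.7) to 192 ± 138 CPM in breast Treg (range 29.5 to 421; log2 fold change 4.95 ± 0.60, adjusted p = 2.28e-05). FOXP3 rose 66.3-fold from 2.14 ± 1.60 to 143 ± 92.2 CPM (log2 fold change 6.05 ± 0.73, adjusted p = 2.28e-05) and IL2RA 9.83-fold from 32.1 ± 20.6 to 316 ± 175 CPM (adjusted p = 5.52e-04). TNFRSF9 rose 47.7-fold to 237 ± 277 CPM (log2 fold change 5.58 ± 0.77, and 4.71 ± 0.68 without breast Treg replicate 3) and CPNE2, a calcium-dependent membrane-binding protein, 21.2-fold to 94.5 ± 68.0 CPM. CD177 had 1 count over all breast Tconv, a ratio of 750.1 with a counting interval of 134 to 29669 (adjusted p = 4.74e-04), and averaged 8.87 ± 7.57 CPM in breast Treg. SLAMF7, a receptor of activated lymphocytes, fell 18.9-fold from 39.9 ± 25.3 to 2.08 ± 2.31 CPM (adjusted p = 0.00259), and GZMH and GZMK, both granzymes, fell with log2 fold changes of -6.03 ± 1.23 and -4.17 ± 0.87. EPHA1-AS1, which overlaps other genes in antisense, was 6.54-fold lower and HNRNPA1P21 48.0-fold higher, and the signal of both is uncertain. IL7R had a log2 fold change of -1.78 ± 0.42 (adjusted p = 0.0605, and 0.0298 with the replicate block) and CD4 one of 0.84 ± 0.43 (adjusted p = 0.355).

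In breast Treg, 33 of 24752 genes rose and 9 fell against breast Tconv (edgeR; 3802 at a raw p under 0.05, 1238 expected). Limma voom turned the balance, with 33 that rose and 183 that fell, while DESeq2 called 1337 and 164. Fits without breast Tconv replicate 3, 4, 7 or 9 gave 24, 26, 25 and 24 genes, and fits without breast Treg replicate 7, 8 or 9 gave 290, 482 and 264. GZMH lost its call without breast Tconv replicate 2 or breast Treg replicate 3 and with the replicate block (adjusted p = 0.0686), and GZMK without breast Tconv replicate 2, 3 or 4 or breast Treg replicate 2. A fit of only these groups called 6 genes, all of which rose, among them CCR8, FOXP3, TNFRSF9 and CPNE2. SLAMF7, GZMH, GZMK, EPHA1-AS1 and HNRNPA1P21 lost their call in it, and not all of IL2RA, CD177, LAYN and PKM kept theirs. Of 15 Treg identity genes 6 rose and all 15 passed when adjusted over the list alone, among them IKZF4, a partner of FOXP3, with a log2 fold change of 3.82 ± 0.64. Of 15 genes reported for tumor Treg elsewhere, 3 rose and 14 passed when adjusted over the list alone, with LAYN at 15.8 against 0.719 CPM (adjusted p = 0.0221, and 0.0601 with the replicate block). Of 12 genes low in Treg 9 fell when adjusted over the list alone, among them IFNG, the cytokine interferon gamma, at 4.47 against 63.9 CPM and IL2 at 10.2 against 90.4 CPM. Of 16 glycolysis genes PKM rose (log2 fold change 1.57 ± 0.34, adjusted p = 0.0414, and 0.0686 with the replicate block), 10 passed when adjusted over the list alone and all 16 were higher, with a median of 0.97. These 4 lists passed camera under both correlations (estimated-correlation adjusted p = 8.07e-04, 9.16e-04, 0.00252 and 0.0465), the last with 0.0536 under the replicate block. Of 12 CD8 T and NK cell markers 1 fell and 5 passed when adjusted over the list alone (median -1.73, estimated-correlation adjusted p = 0.0465, 0.0608 with the replicate block and 0.109 without libraries of high epithelial score). Of the genes called in breast and tested on both platforms, 15 of 23 that rose had also risen and 1 of 3 that fell had also fallen in tumor Treg on Illumina, with 0.189 and 0.00499 expected.

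Tumor Treg were then compared with breast Treg on Illumina (n = 3 and 6), in a fit without a block. These groups share 1 replicate number. No gene passed an adjusted p of 0.05 in edgeR, where 3060 genes had a raw p under 0.05 against 1238 expected and the lowest adjusted p was 0.0985. DESeq2 called 912 genes and limma voom 29. Without breast Treg replicate 7 or 9, edgeR called 1 and 2 genes. CCR8 averaged 546 ± 118 CPM in tumor Treg and 192 ± 138 CPM in breast Treg (log2 fold change 1.51 ± 0.60, adjusted p = 0.334), CD177 averaged 36.8 ± 30.3 and 8.87 ± 7.57 CPM (2.04 ± 0.90, adjusted p = 0.372), IL2RA 746 ± 119 and 316 ± 175 CPM (1.24 ± 0.54, adjusted p = 0.368), and FOXP3 257 ± 110 and 143 ± 92.2 CPM (0.85 ± 0.70, adjusted p = 0.654). Among the interferon response genes all 20 were higher in tumor Treg, with a median log2 fold change of 2.93 (1.36 with the replicate block), and 18 passed when adjusted over the list alone, among them OASL at 468 against 28.1 CPM, RSAD2, an antiviral enzyme (log2 fold change 5.13 ± 1.39), IFIT3 at 656 against 22.9 CPM and MX1 at 1298 against 159.8 CPM. The list passed camera (adjusted p = 9.98e-15) and had an adjusted p = 0.199 with an estimated correlation. The 3 tumor Treg libraries also differed in quality measures, with 26.5 to 27.4% of reads not aligned uniquely against 31.0 to 36.3% in breast Treg. Mitochondrial counts were 2.15 to 3.49% of gene counts against 3.83 to 12.1%. CD177 negative and positive tumor Treg had 30.2 to 35.5% and 29.7 to 34.1% of reads not aligned uniquely. Their mitochondrial shares were 5.25 to 11.1% and 4.21 to 11.9%. These ranges overlap those of breast Treg, so the difference belongs to the 3 libraries and not to all tumor Treg. All 13 mitochondrially encoded genes were lower in the 3 tumor Treg libraries than in breast Treg, with a median of -1.03 (camera adjusted p = 1.30e-06; adjusted p = 0.246 with an estimated correlation). All 15 genes reported for Treg of other tumors were higher, 9 when adjusted over the list alone, with a median of 1.70 and MAGEH1, VDR and SLC35F2 ahead, the last at 137 against 34.9 CPM. That list passed under both correlations (estimated-correlation adjusted p = 0.0188), with 0.120 in that test under the replicate block.

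Other lists were also compared between tumor Treg and breast Treg on Illumina, where no single gene passed the threshold over all genes. Of 14 checkpoint genes 11 were higher, with a median of 1.34 and LAG3, an inhibitory receptor, at 145 against 6.95 CPM (camera adjusted p = 7.31e-04; adjusted p = 0.224 with an estimated correlation). Of 13 naive and lymph-node homing genes 11 were lower, with TCF7 at 19.5 against 100.2 CPM (camera adjusted p = 0.00333; adjusted p = 0.199 with an estimated correlation; 0.0900 with the replicate block). Among 20 chemokine receptors, CCR1 passed when adjusted over the list alone, at 67.4 against 5.01 CPM. The list had a median of 0.13, a mean of -0.02 and an upward camera test (adjusted p = 0.136, and 7.47e-04 with the replicate block). All 16 epithelial markers were lower in tumor Treg, none past the threshold, with a median of -4.23 (-4.12 at bounds), KRT14 at 0.585 against 42.2 CPM and CLDN4 at 0.899 against 60.9 CPM. All 17 fibroblast and endothelial markers were lower too, with a median of -2.19 and DCN, a matrix proteoglycan, at 27.6 against 476 CPM. Camera adjusted p-values of both were 1.06e-07 and 6.28e-06, and each had an adjusted p = 0.246 or 0.257 with an estimated correlation.

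Tconv of tumor and breast gave no called gene in edgeR either (n = 9 and 6; 1187 at a raw p under 0.05, 1238 expected, lowest adjusted p 0.118). These groups share 5 replicate numbers, and the fit had no block. DESeq2 called 31 genes, limma voom 0, and the replicate block 2. Without tumor Tconv replicate 9 or 10, edgeR called 1 gene each. FOXP3 averaged 6.87 ± 5.91 in tumor Tconv and 2.14 ± 1.60 CPM in breast Tconv (log2 fold change 1.67 ± 0.58, adjusted p = 0.730), and CCR8 averaged 15.9 ± 6.07 and 6.20 ± 5.27 CPM (1.35 ± 0.49, adjusted p = 0.778). All 20 interferon response genes were higher in tumor Tconv, with a median of 2.50 (1.09 with the replicate block), and 15 passed when adjusted over the list alone, with ISG15, an interferon-induced modifier, at 361 against 31.0 CPM. Of 24 dissociation and immediate early genes 23 were higher and 3 passed when adjusted over the list alone, all heat shock genes (HSPA1B, HSPA1A and HSPA6), the first at 73.3 against 3.81 CPM (adjusted p over all genes 0.548, and 9.00e-04 with the replicate block). Of 21 effector cytokine genes 17 were higher, none past the threshold, with CXCL13, a chemokine that attracts B cells, at 844 against 62.5 CPM. These lists passed camera under both correlations, with adjusted p = 0.0415, 0.00677 and 0.00677 under the estimated one, the first with 0.0661 without libraries of high epithelial score.

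Whether the tumor effect differed between Treg and Tconv was tested as an interaction of the 4 Illumina groups (n = 3, 6, 9 and 6). LINC01055, a long noncoding RNA chosen after its values were seen, was the 1 called gene, with a log2 fold change of 9.81 ± 1.65 (adjusted p = 0.0309). It lost its call without any one of 16 of the 24 libraries (count 0 without tumor Treg replicate 1 or 8, tumor Tconv replicate 1, 2, 3, 6, 8 or 10, breast Treg replicate 2, 3, 4, 7, 8 or 9, or breast Tconv replicate 3 or 9) and with the replicate block (adjusted p = 0.889), where 0 genes passed. DESeq2 called 96 genes, of which 7 rose and 89 fell, and limma voom 1, another than LINC01055, and 1585 genes had a raw p under 0.05 in edgeR. The interferon genes, all higher in tumor in both cell types, had an interaction median of 0.45 (camera adjusted p = 0.0485; adjusted p = 0.834 with an estimated correlation; camera 0.0732 with the replicate block and 0.411 without libraries of high epithelial score). Of 13 naive and lymph-node homing genes, 12 had a lower tumor effect in Treg than in Tconv, with a median of -1.73, and TCF7 and KLF2 passed when adjusted over the list alone (-2.95 ± 0.85 and -3.11 ± 1.04). That list passed under both correlations, with an adjusted p = 0.0245 under the estimated one and 0.0710 in that test with the replicate block.

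**Figure D3:**
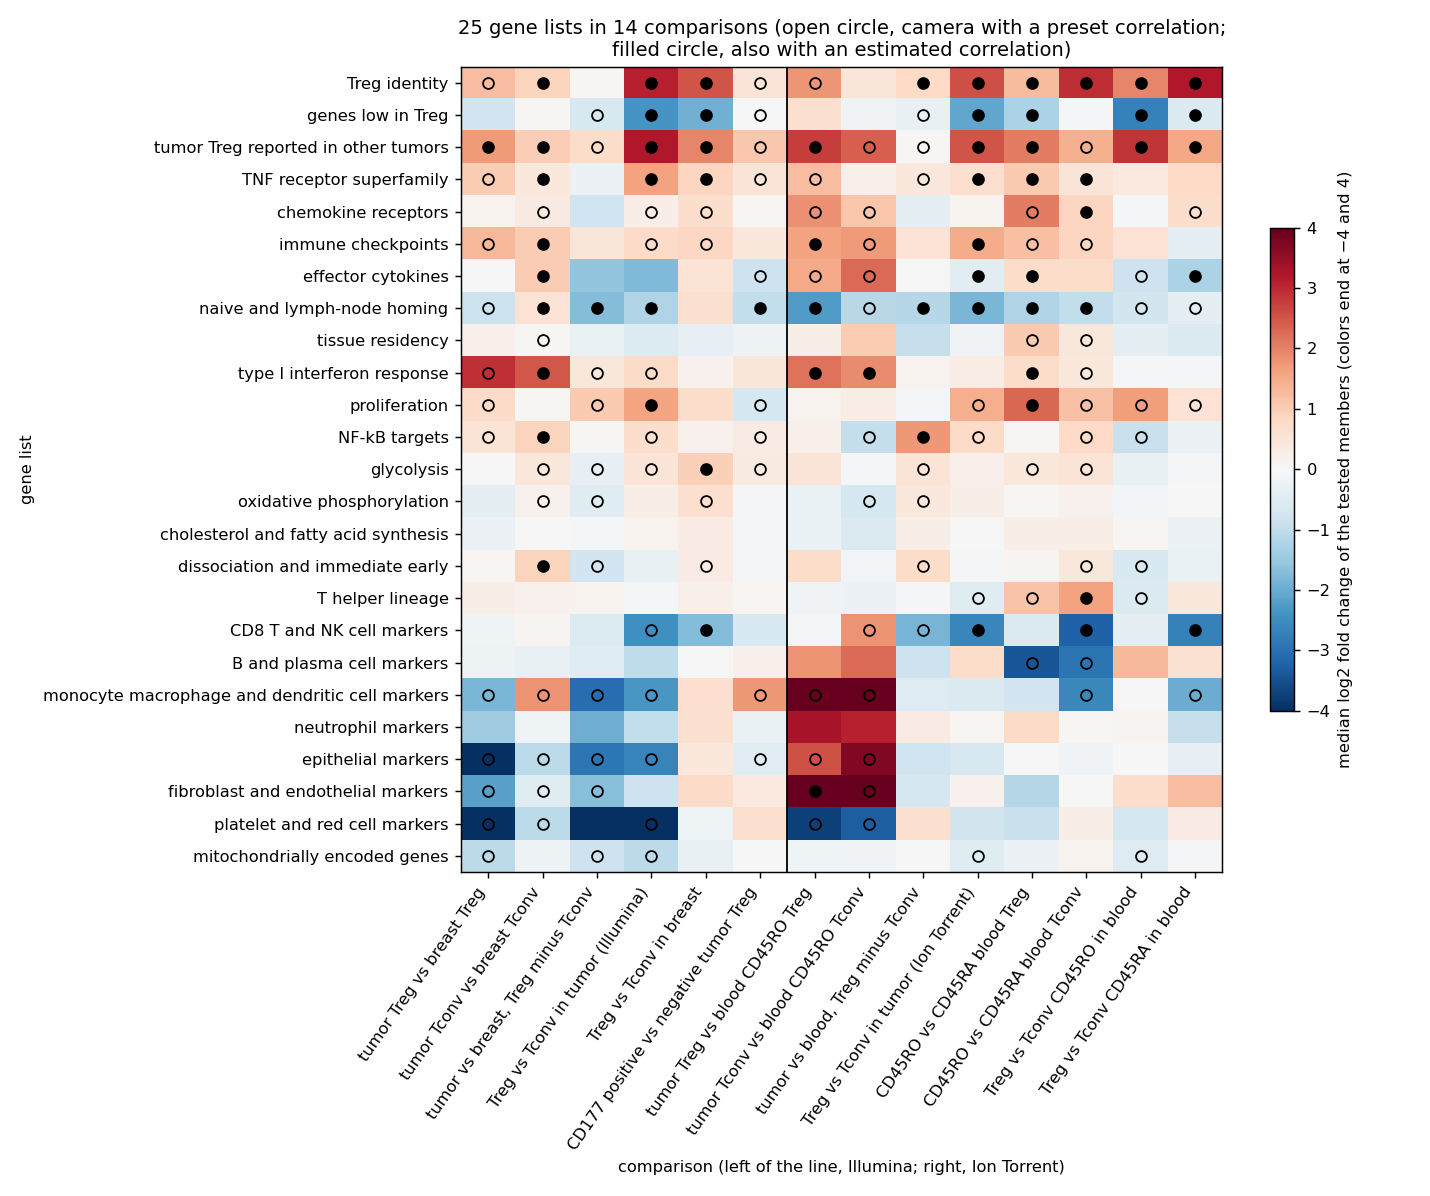
Median log2 fold change of each of 25 gene lists (vertical) in each comparison (horizontal; Illumina left of the line, Ion Torrent right), with colors ending at -4 and 4. Open circles mark lists past an adjusted p of 0.05 in camera with the preset correlation and filled circles those also past it with an estimated correlation, such as the interferon list in tumor against breast Tconv (median 2.50).

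CD177 positive and CD177 negative tumor Treg of the same replicate numbers were compared on Illumina (n = 5 each), in a fit without a block. CD177 itself, the marker of the sort, averaged 274 ± 185 CPM in positive cells (range 34.5 to 488) and 0.908 ± 0.855 CPM in negative cells (range 0 to 2.15), 296-fold higher (log2 fold change 8.21 ± 1.15, adjusted p = 0.00108), and was the 1 called gene in edgeR (1646 at a raw p under 0.05, 1238 expected). DESeq2 called 39 genes, 15 higher and 24 lower, and limma voom 2, while an edgeR fit of these 10 libraries alone called 0. With the replicate block CD177 was again the 1 called gene. CCR8 averaged 801 ± 412 and 371 ± 159.7 CPM (log2 fold change 1.11 ± 0.56, adjusted p = 0.776), IL2RA 769.9 ± 452 and 432 ± 153 CPM (0.83 ± 0.51, adjusted p = 0.872) and FOXP3 397 ± 195 and 263 ± 93.1 CPM (0.60 ± 0.64, adjusted p = 0.996). Each of these 3 genes was higher in CD177 positive cells at 4 of 5 replicate numbers and lower at replicate 10, whose positive library had 56.8 CPM of FOXP3 and an epithelial score of 6.85. TNFRSF9 and IL7R had the same pattern. IL7R, which is low in Treg, averaged 674 ± 322 CPM in positive and 527 ± 141 CPM in negative cells, so the pattern is not particular to Treg genes. Of 13 naive and lymph-node homing genes, 10 were lower in CD177 positive cells and 3 passed when adjusted over the list alone, among them TCF7 at 14.7 against 55.5 CPM and BACH2, a repressor that keeps T cells naive, at 1.07 against 5.56 CPM. This list passed under both correlations, with an adjusted p = 0.0497 under the estimated one and 0.121 in that test without libraries of high epithelial score. All 15 genes reported for Treg of other tumors were higher, none past the threshold also when adjusted over the list alone, with a median of 1.07 and IL1R2 at 221 against 56.5 CPM (camera adjusted p = 1.33e-07; adjusted p = 0.152 with an estimated correlation). Of 15 monocyte, macrophage and dendritic cell markers 14 were higher in CD177 positive cells, none past the threshold, with FCER1G at 49.8 against 14.8 CPM (median 1.75; camera adjusted p = 6.99e-08; adjusted p = 0.227 with an estimated correlation).

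Tumor Treg were set against CD45RO blood Treg on Ion Torrent (n = 3 and 4). CCR8 rose 17.6-fold from 44.2 ± 16.0 to 779 ± 73.0 CPM (log2 fold change 4.13 ± 0.53, adjusted p = 2.28e-05), IL2RA rose 2.95-fold from 263 ± 54.8 to 776 ± 152 CPM (adjusted p = 6.98e-04) and FOXP3 3.95-fold from 36.1 ± 20.3 to 143 ± 66.6 CPM (adjusted p = 0.00958). CD177 had 1 count over the blood libraries, a ratio of 2254 with a counting interval of 404 to 89079 (adjusted p = 2.60e-04), at 63.0 ± 17.5 CPM in tumor Treg. ZBED2, a zinc finger factor, rose 34.8-fold from 4.77 ± 1.55 to 169 ± 35.3 CPM (log2 fold change 5.12 ± 0.31, adjusted p = 2.36e-09; chromosome 3, 111592900 to 111595443), and CCL4, a chemokine, rose 192-fold from 0.438 ± 0.237 to 82.8 ± 23.8 CPM. HAVCR2, an inhibitory receptor, rose from 10.2 to 154 ± 20.9 CPM and CCR2, a receptor for monocyte chemokines, 23.9-fold to 94.9 ± 42.3 CPM. The interferon-linked genes IRF2, SAMD9L, OAS2 and PLSCR1 were 6.04-fold (IRF2) to 9.49-fold (PLSCR1) higher, with COPB2 at 5.34-fold and ZNF559 at 7.91-fold. KLF3, a transcription factor of resting T cells, fell 15.5-fold from 143 ± 45.0 to 9.25 ± 2.25 CPM and ITGB7, an integrin of gut homing, 5.96-fold from 84.5 ± 21.7 to 14.2 ± 2.73 CPM. WHAMM, CLEC2B, DDX21, HAUS3, BNIP1 and MPP7 fell by 5.18-fold (BNIP1) to 11.7-fold (WHAMM). SBDS fell 8.50-fold and its near-identical pseudogene SBDSP1 9.51-fold, so reads of both are uncertain. IL7R had a log2 fold change of 0.64 ± 0.34 (adjusted p = 0.159).

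Between tumor and blood Treg, 3367 of 18948 genes rose and 2640 fell (edgeR; 8045 at a raw p under 0.05, 947 expected), and all genes named by the rule kept their call without any one library. Scaled by total counts alone, 71.7% of called genes rose against 56.1% with the scaling used here. Of 19 interferon response genes 15 rose and 1 fell, with RSAD2 at 50.6 against 2.05 CPM. Of 14 genes reported for Treg of other tumors 13 rose and all 14 passed when adjusted over the list alone, with VDR at 153 against 6.38 CPM and MAGEH1 at 198 against 38.4 CPM. Of 9 checkpoint genes 5 rose, TIGIT and BTLA by log2 fold changes of 2.84 ± 0.30 and 4.45 ± 0.49. Of 10 naive and lymph-node homing genes 8 fell and 9 passed when adjusted over the list alone, with TCF7 at 27.8 against 156 CPM and KLF2 at 2.97 against 21.9 CPM. These 4 lists passed camera under both correlations (estimated-correlation adjusted p = 0.00245, 0.0104, 0.00951 and 0.00545). Treg identity genes rose in 9 of 12 cases, with an adjusted p = 0.0539 with an estimated correlation (camera adjusted p = 3.16e-05). All 13 fibroblast and endothelial markers rose, FN1 and SPARC reaching 105 and 257 CPM in tumor Treg from 2.21 and 0.507 CPM (median 7.28, or 7.02 at bounds; estimated-correlation adjusted p = 0.0104). Of 14 monocyte, macrophage and dendritic cell markers 9 rose and 12 passed when adjusted over the list alone. CD14 reached 13.3 CPM, and C1QB, without counts in blood Treg, was at least 104-fold higher (median 5.26, or 4.40 at bounds; camera adjusted p = 3.16e-05; adjusted p = 0.292 with an estimated correlation). Of 21 dissociation and immediate early genes 10 rose and 3 fell, with FOS at 359 against 22.3 CPM (camera adjusted p = 0.119).

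Tumor Tconv were set against CD45RO blood Tconv on Ion Torrent (n = 5 and 2). CCL4 rose 289-fold from 1.02 ± 0.616 to 303 ± 113 CPM (log2 fold change 8.18 ± 0.74, adjusted p = 9.83e-07) and IRF2, a regulator of interferon genes, 9.52-fold from 14.8 ± 2.55 to 141 ± 16.7 CPM (log2 fold change 3.25 ± 0.26, adjusted p = 1.79e-07; chromosome 4, 184387713 to 184474580). SAMD9L, ASXL2 and OAS2 rose 13.1-fold, 5.89-fold and 8.17-fold. GABARAPL1, an autophagy gene, fell from 139 ± 12.9 to 10.7 ± 3.01 CPM (log2 fold change -3.70 ± 0.24), and WHAMM, RNF125, SBDS and SBDSP1 fell by 6.18-fold (SBDSP1) to 8.54-fold (WHAMM), SBDS and SBDSP1 again being uncertain. IL7R rose 2.48-fold from 1357 ± 155 to 3362 ± 2089 CPM (adjusted p = 0.0222). CD177, without counts in blood Tconv, averaged 1.36 ± 2.64 CPM in tumor Tconv (adjusted p = 0.110), with 6.07 CPM in replicate 14 and 0.0631 to 0.486 CPM in the others. CCR8 had a log2 fold change of 1.12 ± 0.58 (adjusted p = 0.167) and FOXP3 one of 0.40 ± 0.66 (adjusted p = 0.684). Of 18948 genes 2655 rose and 2089 fell (edgeR; 7229 at a raw p under 0.05), and fits without blood Tconv replicate 17 or 18 gave 1943 and 1708. Scaling by total counts alone moved the share that rose from 56.0% to 71.7%. Of 19 interferon response genes 13 rose, with RSAD2 at 79.0 against 1.88 CPM (median 1.88; estimated-correlation adjusted p = 0.0150). Of 12 CD8 T and NK cell markers 4 rose and 5 passed when adjusted over the list alone, with EOMES at 40.5 against 0.331 CPM (median 1.78, or 1.58 at bounds; camera adjusted p = 0.0134; adjusted p = 0.233 with an estimated correlation). Of 13 fibroblast and endothelial markers 12 rose, with FN1 at 91.5 against 1.33 CPM (median 7.48, or 7.13 at bounds; camera adjusted p = 6.42e-07; adjusted p = 0.0760 with an estimated correlation). Of 13 NF-kB target genes 1 rose and 6 fell, with TNFAIP3, an inhibitor of this pathway, at 533 against 2047 CPM (camera adjusted p = 0.00296; adjusted p = 0.147 with an estimated correlation).

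The difference between these tumor against blood effects in Treg and in Tconv was tested as an interaction on Ion Torrent (n = 3, 4, 5 and 2). IL4R, the receptor of interleukin 4, was 109 ± 22.3 CPM in tumor Treg and 40.2 ± 14.5 in blood Treg but 56.5 ± 11.8 in tumor Tconv and 194 ± 101 in blood Tconv (log2 interaction 3.22 ± 0.45, adjusted p = 0.00340). BHLHE40, a factor of cytokine-producing T cells, rose from 7.38 ± 3.90 to 65.0 ± 8.49 CPM in Treg, with 139.9 ± 34.0 CPM in tumor and 277 ± 132 CPM in blood Tconv (log2 interaction 4.10 ± 0.59, adjusted p = 0.00340). ZBED2, EPHX2 and DENND5A had interactions of 2.83 ± 0.41, 3.32 ± 0.54 and 3.26 ± 0.54. GZMA was 145 ± 49.1 CPM in tumor Tconv and 7.81 ± 1.19 in blood Tconv, but 4.43 ± 1.03 and 6.39 ± 3.43 CPM in Treg (log2 interaction -4.77 ± 0.56, adjusted p = 6.32e-04). TC2N, CLEC2B, ITGB7 and GIMAP1 had interactions of -3.27 ± 0.49, -2.57 ± 0.45, -1.87 ± 0.34 and -3.04 ± 0.56. CCR8, past the threshold in Treg alone, had an interaction of 3.02 ± 0.72 (adjusted p = 0.140), IL2RA one of 1.42 ± 0.45 (adjusted p = 0.357) and FOXP3 one of 1.58 ± 0.84 (adjusted p = 0.691). In all 15 of 18948 genes were positive and 9 negative (edgeR; 1419 at a raw p under 0.05), against 67 and 81 in DESeq2. Fits without tumor Treg replicate 14 or 15 or blood Tconv replicate 17 gave 11, 12 and 15 genes, and without blood Tconv replicate 18 only 1, when all named genes but GZMA lost their call. DENND5A also lost it without tumor Treg replicate 15 or blood Tconv replicate 17. CLEC2B and GIMAP1 also lost it without tumor Treg replicate 14 or 15 or blood Tconv replicate 17, and ITGB7 without tumor Treg replicate 14 or 16 or blood Tconv replicate 17, and with the replicate block (adjusted p = 0.0652). A fit of only these groups called 9 genes, without EPHX2, DENND5A, CLEC2B, ITGB7 and GIMAP1. NF-kB targets had a positive interaction, with 10 of 13 positive, a median of 1.74 and 5 past the threshold when adjusted over the list alone, led by TRAF1 and TNFAIP3 (estimated-correlation adjusted p = 0.0111, and 0.0596 with the replicate block). Of 10 naive and lymph-node homing genes CCR7 passed (-2.48 ± 0.49; adjusted p = 0.108 with the replicate block), 3 when adjusted over the list alone, with a median of -1.16 (estimated-correlation adjusted p = 0.0163, and 0.0596 with the replicate block).

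**Figure D4:**
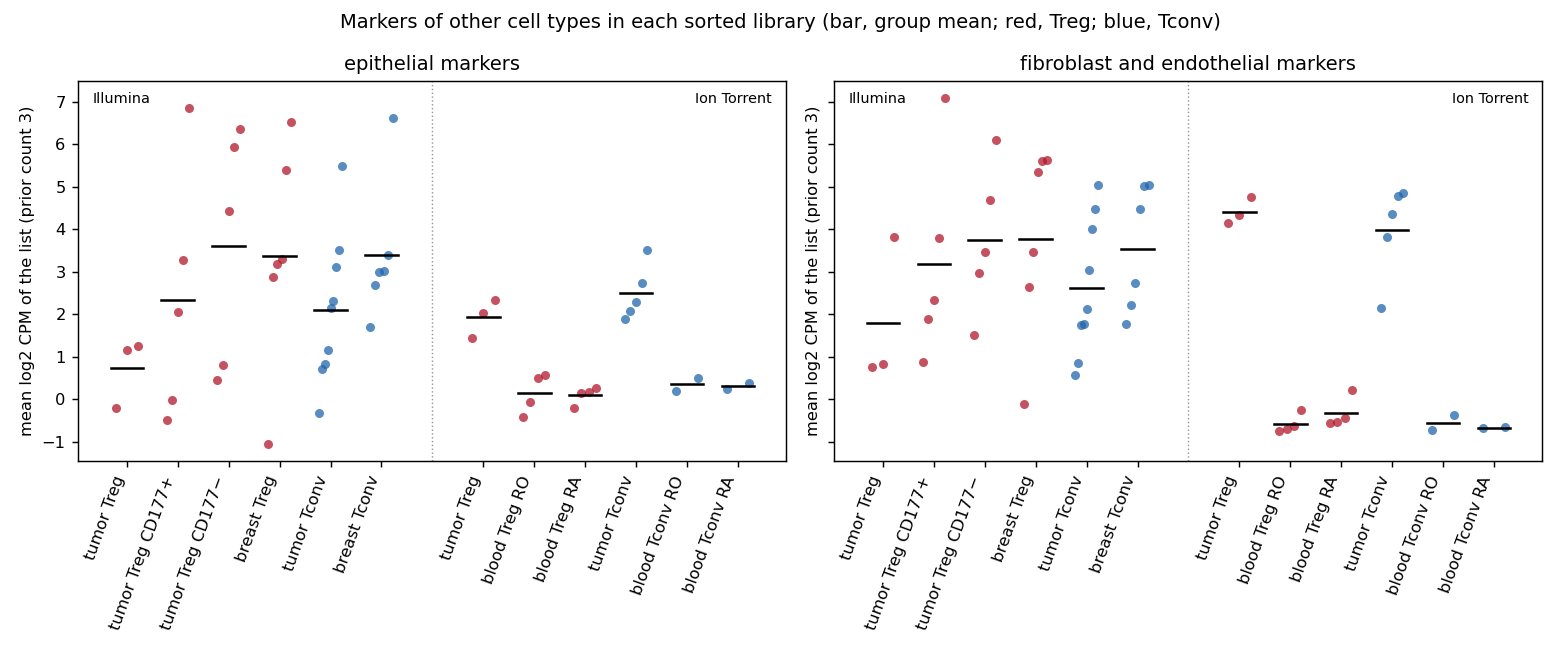
Mean log2 CPM (prior count 3) of the epithelial (left) and the fibroblast and endothelial (right) marker lists in each library, by sorted group, with bars at group means. The fibroblast and endothelial score averaged 4.42 in tumor Treg and -0.58 in CD45RO blood Treg on Ion Torrent, and 1.80 in tumor Treg and 3.77 in breast Treg on Illumina.

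Activated CD45RO and resting CD45RA Treg of blood, from the same replicate numbers, were compared on Ion Torrent (n = 4 each), in a fit without a block. DUSP4, a phosphatase of MAP kinases, rose from 12.9 ± 9.52 to 169 ± 6.82 CPM (log2 fold change 3.71 ± 0.42, adjusted p = 4.67e-05; chromosome 8, 29333064 to 29350668) and FAS, a death receptor, 4.85-fold from 47.5 ± 18.3 to 231 ± 47.0 CPM (adjusted p = 7.26e-05). CCR8 rose 14.5-fold from 3.04 ± 1.85 to 44.2 ± 16.0 CPM (adjusted p = 2.84e-04) and IL2RA 2.35-fold from 112 ± 34.6 to 263 ± 54.8 CPM (adjusted p = 0.00941), while FOXP3 averaged 36.1 ± 20.3 and 14.4 ± 4.96 CPM (log2 fold change 1.33 ± 0.52, adjusted p = 0.122). SGMS1, WEE1, FAM129A, C12orf75, TBK1, MYO5A, CTNNA1 and ANXA2 rose by 2.92-fold (MYO5A) to 9.83-fold (FAM129A). PLAC8 fell 7.42-fold from 79.1 ± 27.0 to 10.6 ± 2.26 CPM, TGFBR2, a receptor of TGF-beta, 3.99-fold from 204 ± 38.4 to 51.3 ± 5.39 CPM and IL7R 2.40-fold from 1218 ± 202 to 508 ± 72.8 CPM (adjusted p = 0.0167). SCML1, SLC40A1, TCEA3, RASGRF2, EXPH5, DENND5A, CERS6 and PLXDC1 fell by 5.91-fold (CERS6) to 17.1-fold (TCEA3). In all 860 of 18948 genes rose and 730 fell (edgeR; 4372 at a raw p under 0.05), and fits without CD45RA Treg replicate 17 or 18 gave 966 and 1053, with all genes named by the rule kept.

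Gene lists were also compared between the activated and the resting blood Treg. Of 19 proliferation genes 13 rose and 18 passed when adjusted over the list alone, with MKI67, a marker of cycling cells, at 57.3 against 3.70 CPM and TOP2A at 72.6 against 10.6 CPM. Of 14 genes reported for Treg of tumors 8 rose, 9 when adjusted over the list alone, with CXCR6 at 71.6 against 5.93 CPM and TNFRSF9 at 43.5 against 4.45 CPM. Of 10 naive and lymph-node homing genes 4 fell, 7 when adjusted over the list alone, with TCF7 at 156 against 552 CPM and BACH2 at 14.6 against 90.9 CPM. These 3 lists had adjusted p = 0.0360, 0.0288 and 0.0288 with an estimated correlation, and 0.0664 each in that test with the replicate block. Of 17 chemokine receptors 7 rose and 1 fell, and of 11 T helper lineage genes 5 rose, with CCR6, a receptor of Th17 cells, at 314 against 39.5 CPM and GATA3 at 97.6 against 20.2 CPM (adjusted p = 0.0648 and 0.0619 with an estimated correlation; camera adjusted p = 9.14e-06 and 0.00725). Of 8 B and plasma cell markers 4 fell, with BANK1 at 1.17 against 48.7 CPM (median -3.41; camera adjusted p = 0.0209; adjusted p = 0.212 with an estimated correlation).

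The same states were compared in blood Tconv of the same replicate numbers on Ion Torrent (n = 2 each), in a fit without a block. ITGB1, an integrin of memory T cells, rose 13.6-fold in CD45RO cells from 24.1 ± 5.98 to 328 ± 45.0 CPM (log2 fold change 3.77 ± 0.45, adjusted p = 2.52e-04; chromosome 10, 32900319 to 33005792). FAS rose 10.2-fold, FAM129A 51.4-fold, DUSP4 54.6-fold and IL2RA 13.8-fold, the last from 2.06 ± 0.763 to 28.4 ± 4.38 CPM. CCR8, without counts in CD45RA Tconv, was at least 78.2-fold higher (adjusted p = 0.00259), and FOXP3 averaged 4.13 ± 0.110 and 0.249 ± 0.199 CPM (adjusted p = 0.0954). CDCA7L fell 8.70-fold from 57.8 ± 18.9 to 6.65 ± 3.82 CPM and TGFBR2 3.25-fold, with PAFAH2, METTL6 and CACHD1 lower by 2.87-fold (PAFAH2) to 66.5-fold (CACHD1). Of 18948 genes 141 rose and 25 fell (edgeR; 1958 at a raw p under 0.05). Fits without CD45RO Tconv replicate 17 or 18 gave 84 and 69 genes and without CD45RA Tconv replicate 17 or 18 gave 27 and 28, while the replicate block gave 470. CDCA7L lost its call in 2 of these 4 fits and PAFAH2, TGFBR2, METTL6 and CACHD1 in all 4. PAFAH2 and METTL6 also lost it without the filter and in a fit of only these groups. Of 11 T helper lineage genes CCR6 and GATA3 rose and 6 passed when adjusted over the list alone, with CCR6 at 325 against 3.59 CPM. GATA3 had an adjusted p = 0.0200, and 0.0579 with the replicate block. Of 12 CD8 T and NK cell markers all were lower, GZMH past the threshold and 6 when adjusted over the list alone, with NKG7 at 5.87 against 37.9 CPM (its adjusted p over all genes 0.0709, and 0.0134 with the replicate block; list median -3.22, or -2.84 at bounds). Of 12 Treg identity genes 4 rose and 9 passed when adjusted over the list alone, with CCR4, a receptor for skin and tissue homing, at 174 against 3.32 CPM. These 3 lists passed camera under both correlations (estimated-correlation adjusted p = 0.00313, 0.00313 and 0.00138).

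Treg and Tconv of blood were compared within each state on Ion Torrent (Treg n = 4, Tconv n = 2), in a fit without a block. The replicate numbers of Tconv are also among those of Treg. Among CD45RO cells IL2RA rose 9.26-fold from 28.4 ± 4.38 to 263 ± 54.8 CPM (log2 fold change 3.21 ± 0.41, adjusted p = 2.04e-04) and FOXP3 8.75-fold from 4.13 ± 0.110 to 36.1 ± 20.3 CPM (adjusted p = 0.0353). BLM, SMC6 and GBP5, an interferon-induced GTPase, rose by 3.24-fold (SMC6) to 5.60-fold (GBP5). BHLHE40 fell 36.8-fold from 277 ± 132 to 7.38 ± 3.90 CPM (log2 fold change -5.20 ± 0.48, adjusted p = 5.42e-06), RBMS1, an RNA-binding protein, 6.23-fold from 102 ± 25.5 to 16.4 ± 1.63 CPM, and SLC40A1, PLAC8 and WNT7A by 7.79-fold (PLAC8) to 33.5-fold (WNT7A). CCR8 had a log2 fold change of 1.71 ± 0.61 (adjusted p = 0.195) and IL7R one of -1.42 ± 0.37 (adjusted p = 0.0576, and 0.0153 with the replicate block). Of 18948 genes 88 rose and 226 fell (edgeR; 2705 at a raw p under 0.05), against 496 and 376 in DESeq2. Fits without CD45RO Tconv replicate 17 or 18 gave 157 and 54, and the replicate block 678. BLM, SMC6 and GBP5 lost their call without CD45RO Tconv replicate 18, and GBP5 also without 17. A fit of only these groups called 62 genes, without BLM and SMC6. Of 7 genes low in Treg 5 fell and 6 passed when adjusted over the list alone, with ANK3 at 11.8 against 208 CPM and NELL2 at 6.23 against 125 CPM (estimated-correlation adjusted p = 2.01e-05). Of 12 Treg identity genes 5 rose and 6 passed when adjusted over the list alone (estimated-correlation adjusted p = 0.0371, and 0.161 with the replicate block).

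Among CD45RA blood cells IL2RA rose 54.5-fold in Treg from 2.06 ± 0.763 to 112 ± 34.6 CPM (log2 fold change 5.77 ± 0.50, adjusted p = 3.05e-06), TIGIT 21.4-fold from 5.67 ± 1.96 to 122 ± 29.9 CPM (adjusted p = 1.75e-05) and FOXP3 57.3-fold from 0.249 ± 0.199 to 14.4 ± 4.96 CPM (adjusted p = 0.0117; n = 4 and 2). IKZF2 rose 20.9-fold. CEACAM4 had 1 count in CD45RA Tconv, a ratio of 354 with a counting interval of 63.4 to 14019, and DNAH8, without counts there, was at least 109-fold higher. CCR8, also without counts in CD45RA Tconv, was at least 17.1-fold higher (adjusted p = 0.0546). NKG7, a granule protein of cytotoxic cells, fell 14.2-fold from 37.9 ± 8.99 to 2.66 ± 1.86 CPM (adjusted p = 0.00233), RBMS1 fell 4.05-fold, and PLAUR, CDK6 and GNLY fell by 2.91-fold (CDK6) to 14.8-fold (PLAUR). Of 18948 genes 50 rose and 21 fell (edgeR; 1589 at a raw p under 0.05), against 51 and 74 in limma voom. Fits without CD45RA Tconv replicate 17 or 18 or CD45RA Treg replicate 20 gave 5, 17 and 46 genes, and the replicate block 145. Without CD45RA Tconv replicate 17, CEACAM4, DNAH8, IKZF2, NKG7, PLAUR, CDK6 and GNLY lost their call. CDK6 also lost it without CD45RA Tconv replicate 18 or CD45RA Treg replicate 20, and GNLY without the last or with the block (adjusted p = 0.0522). PLAUR lost it in limma voom, and PLAUR and GNLY in a fit of only these groups. Of 12 Treg identity genes 4 rose and 7 passed when adjusted over the list alone. Of 12 CD8 T and NK cell markers 4 fell and 7 passed when adjusted over the list alone, and of 14 effector cytokine genes CCL4 fell and 6 passed when adjusted over the list alone. These 3 lists passed under both correlations (estimated-correlation adjusted p = 1.32e-04, 3.10e-04 and 6.24e-04).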

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

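None of these tests of single libraries and of interactions, but the replicate block on Ion Torrent, was chosen only after results were seen. In 11 of 88 groups and measures 1 library stood apart from the rest by a Dixon test. Its limits set apart about 1 in 20 by chance only for independent values with a normal spread. CPM and gene counts were tested without logs and the measures share libraries, so the 11 cannot be read as an excess over chance. On Illumina, tumor Tconv replicate 8 had 33795 detected genes (others 23318 to 28146). Tumor Tconv replicate 1 had a FOXP3 level of 21.2 CPM (others 2.15 to 9.07). Tumor Tconv replicate 3 had a CCR8 level of 30.2 CPM (others 10.5 to 18.6). Breast Tconv replicate 8 had an epithelial marker score of 6.62 (others 1.72 to 3.41). Breast Tconv replicate 2 had an IL2RA level of 72.4 CPM (others 16.5 to 34.0). Among CD177 positive tumor Treg, FOXP3 was 56.8 CPM in 1 library and 416 to 522 CPM in the others.

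On Ion Torrent, tumor Tconv replicate 13 had an IL7R level of 6973 CPM (others 1732 to 3241). Tumor Tconv replicate 14 had a CD177 level of 6.07 CPM (others 0.0631 to 0.486) and a CCR8 level of 72.0 CPM (others 15.1 to 23.9). Replicate 14 also had the highest FOXP3 and TNFRSF9 levels of its group, 14.7 and 55.2 CPM, and the lowest IL7R level, 1732 CPM. CD45RA blood Treg held a library with 27953 detected genes (others 21847 to 22487), and CD45RO blood Treg an IL2RA level of 344 CPM (others 231 to 244). The cause of these values was not tested.

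In edgeR the tumor against breast effect differed between Treg and Tconv for 1 gene on Illumina, which lost its call with the replicate block and without any one of 16 of 24 libraries. The tumor against blood effect differed for 24 genes on Ion Torrent. On Ion Torrent the interactions were 3.22 for IL4R, 4.10 for BHLHE40, 2.83 for ZBED2, 3.32 for EPHX2 and 3.26 for DENND5A in favor of Treg. GZMA (-4.77), TC2N (-3.27), CLEC2B (-2.57), ITGB7 (-1.87) and GIMAP1 (-3.04) went the other way. Of these only GZMA kept its call whichever library was left out, and ITGB7 lost its call with the replicate block.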

How the results depend on the processing

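The tests with the epithelial marker score, without high-epithelial libraries, without the sparse library, of lists with a block and of the Ion Torrent interaction with a block were chosen only after results were seen. Groups of 2 to 9 libraries limit every count, the cause of the shifts was not tested, and no paired analysis was possible of tumor against blood Treg or Tconv on Ion Torrent because these share no replicate number. Counts are called genes, with those that rose and fell in brackets. The DESeq2 Wald test gave 912 (155 and 757) for tumor against breast Treg, 31 (22 and 9) for Tconv, 96 (7 and 89) for their interaction, 516 (197 and 319) for Treg against Tconv in tumor, 1501 (1337 and 164) in breast and 39 (15 and 24) for CD177. On Ion Torrent it gave 148 (67 and 81) for the interaction, 499 (356 and 143) for CD45RO against CD45RA Tconv, and 872 (496 and 376) and 241 (166 and 75) for CD45RO and CD45RA Treg against Tconv. Limma voom gave 29 (28 and 1), 311 (217 and 94), 216 (33 and 183) and 2 for tumor against breast Treg, Treg against Tconv in tumor and breast, and CD177, then 93 (68 and 25), 1787 (1062 and 725), 375 (248 and 127), 676 (218 and 458) and 125 (51 and 74) for the Ion Torrent interaction, Treg against Tconv in tumor, CD45RO against CD45RA Tconv, and CD45RO and CD45RA Treg against Tconv. Only the groups compared gave 2 for the Illumina interaction, 654 (387 and 267) and 6 for Treg against Tconv in tumor and breast, 0 for CD177, 9 for the Ion Torrent interaction, 974 (524 and 450) and 387 (268 and 119) for CD45RO against CD45RA Treg and Tconv, and 62 (10 and 52) and 111 (68 and 43) for CD45RO and CD45RA Treg against Tconv. No filter gave 70 (42 and 28) for the Ion Torrent interaction, 252 (209 and 43) for CD45RO against CD45RA Tconv and 119 (72 and 47) for CD45RA Treg against Tconv. The stricter filter gave 1 for tumor against breast Tconv and 99 (73 and 26) for breast Treg against Tconv, where DESeq2 size factors gave 169 (147 and 22). The replicate block gave 2 for tumor against breast Tconv, 0 for the Illumina interaction, 71 (57 and 14) for Treg against Tconv in tumor, 470 (339 and 131) for CD45RO against CD45RA Tconv, and 678 (243 and 435) and 145 (77 and 68) for CD45RO and CD45RA Treg against Tconv. It changed no other printed call than those given with the results. CD177 fractions as tumor Treg gave 308 (70 and 238) against breast Treg and 1211 (548 and 663) against tumor Tconv. The epithelial covariate gave 1, 2 and 2 for tumor against breast Treg, tumor against breast Tconv and CD177, and with the sparse library left out 1 for tumor against breast Treg, 0 for the interaction and 313 (232 and 81) for Treg against Tconv in tumor. Without high-epithelial libraries there were 1 for tumor against breast Tconv, 0 for the interaction and 213 (187 and 26) for breast Treg against Tconv. Of the gene list tests, 63 passed with an estimated correlation and 101 with fry, against 175.

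Leaving out 1 library at a time gave 0 to 2 genes for tumor against breast Treg, 0 to 1 for Tconv and for the interaction, 70 to 139 and 24 to 482 for Treg against Tconv in tumor and breast, and 1 throughout for CD177. On Ion Torrent it gave 4378 to 5624 and 1708 to 5016 for tumor against blood Treg and Tconv, 1 to 31 for the interaction, 529 to 1119 for Treg against Tconv in tumor, 966 to 1632 and 27 to 84 for CD45RO against CD45RA Treg and Tconv, and 54 to 399 and 5 to 55 for CD45RO and CD45RA Treg against Tconv. Of 141 named genes 124 to 141 kept their call when 1 library was left out. Genes of comparisons without that library were not tested again and count as kept, so this range overstates stability. In fits of only the groups compared 122 kept their call. Signs that changed were few. CLDN4 had log2 fold changes of 1.90 against tumor Tconv and 0.88 against breast Treg with CD177 fractions as tumor Treg. FOXP3 in tumor against blood Tconv had -0.16 with limma voom, and -0.27 without tumor Tconv replicate 14 to 0.62 without replicate 12.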

Other observations

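Epithelial and stromal transcripts varied widely within the sorted groups on Illumina, and were higher in tumor than in blood on Ion Torrent. The tests of label order, noisy counts, the breast calls on both platforms, the CD177 call, the sparse library, epithelial RNA and tissue digestion were chosen only after results were seen. The epithelial marker score averaged 0.74 ± 0.81 in tumor Treg (n = 3), 3.38 ± 2.60 in breast Treg (n = 6), 2.11 ± 1.76 in tumor Tconv (n = 9) and 3.41 ± 1.67 in breast Tconv (n = 6) on Illumina. The ranges of most of these groups overlap, but tumor Treg reach 1.25 where breast Tconv start at 1.72. CD177 negative and positive tumor Treg had 3.60 ± 2.80 and 2.34 ± 2.95 (n = 5 each). On Ion Torrent tumor Treg (n = 3) and tumor Tconv (n = 5) had 1.93 ± 0.46 and 2.51 ± 0.65, and the blood groups 0.10 to 0.35.

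Other divisions of the same libraries were used to ask which counts exceed chance. For Treg against Tconv in tumor on Illumina the real division called 148 genes. Of 100 divisions 1 (itself) called as many, and the highest other called 2. The real division was also alone for Treg against Tconv in tumor on Ion Torrent (966, 1 of 56, highest other 222) and CD45RO against CD45RA Treg (1590, 1 of 35, highest other 40). These counts argue against chance but do not exclude it, since most other divisions part fewer pairs of the same number. Tumor and blood Treg share no number. There the real division called 6007 genes, 1 of 35 and the least that 35 divisions allow, and the highest other called 2943. Chance is not excluded for the interaction of tumor against breast in Treg and Tconv (1 gene, 23 of 100, highest other 442). For CD177 fractions the count alone does not exclude chance either (1 gene, 14 of 100, highest other 7). The called gene is CD177, the marker of the sort, and only 1 of 126 divisions (the real one) had as large a difference in its mean log2 level. The sort on CD177 set this outcome, so it cannot decide whether the fractions differ beyond the sort. For tumor against breast Treg (highest other 3126) and Tconv (highest other 1) the real division called 0 genes, so no such count can decide.

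For breast Treg against Tconv 5 of 100 divisions, the real one with its 42 genes among them, called as many (highest other 927), so this count alone does not exclude chance. Of the called genes tested on both platforms, 15 of 23 that rose and 3 of 3 that fell in breast were called the same way in tumors of other donors on Ion Torrent. Only 0.774 and 0.0825 were expected and none went the other way, which argues against chance as the cause of these calls as a set. It does not exclude chance, since the expected numbers treat genes as independent and equally likely to be called, and only 3 fell. For the other called genes chance stays open. Divisions with 3126, 442 or 927 genes, many more than the real ones, point to a structure of the samples other than the groups, and which libraries make it was not tested.

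Where replicate numbers pair libraries, other divisions part fewer pairs and so set numbers against each other more than the real one does. Among divisions parting as many pairs, 1 of 5 was as large for Treg against Tconv in tumor on Illumina (highest other 0), 1 of 4 in breast (highest other 0), 1 of 8 in tumor on Ion Torrent (highest other 0) and 1 of 8 for CD45RO against CD45RA Treg (highest other 0). For the Illumina interaction 2 of 6 were as large (highest other 442) and for CD177 2 of 12 (highest other 1). The numbers of such divisions are too few to exclude chance on their own.

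The Ion Torrent labels of 20609 genes change with the sort order of their names. Protein-coding genes among them correlated with Illumina tumor Tconv levels at 0.931 under names sorted again and at 0.374 under the deposited ones, with 0.276 to 0.366 when moved by 1 or 2 places. Names and counts sorted in different orders fit this, and low or noisy counts are excluded.

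The spread between Illumina libraries has more than 1 source. A single breast Treg library with few detected genes held 76.7% of the leading component. Without it the component correlated at 0.594 with the epithelial marker score (permutation p = 0.00027), and at 0.455 without the 2 farthest libraries. The mitochondrial percent (0.580), the fibroblast and endothelial score (0.551) and the percent of reads outside features (0.460) correlated almost as well. The permutation p treats the 33 libraries as independent, although they come from 10 replicate numbers. Libraries of the same number were correlated, so this p may be too small. Over the means of the 10 numbers the epithelial score had an r of 0.767. The mitochondrial percent had 0.536, the fibroblast and endothelial score 0.728 and the percent outside features 0.441. These values over means were not tested. So epithelial RNA fits as a source, but not as a specific one. With its score as a covariate 1 gene was called between tumor and breast Treg. Whether epithelial RNA keeps the calls few cannot be told apart, since the score differs between these groups and few simulated changes were recovered in this design. Sequencing depth, at -0.346, cannot be told apart either. Differences in the tumors themselves, and in the quality of the tumor Treg libraries, stay open as untested.

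For tumor against blood Treg, 11 pan T cell genes had a median of -0.0678 (quartiles -0.38 and 0.44) where naive genes had -2.27. This argues against dilution by RNA of other cells as the cause of falls as large as those of the naive genes. It does not address smaller falls or RNA of other cells in the blood libraries. Of genes that rose, 22.3% followed the fibroblast and endothelial score on Illumina against 7.59% of uncalled genes, and the dissociation list had an adjusted p of 0.119 (camera), so stromal RNA and tissue digestion cannot be told apart from a change in Treg. Of the genes that rose 48.8% were higher in tumor than in breast Treg on Illumina, and of those that fell 47.4%. These shares cannot decide whether the tumor rather than any tissue is the source. The Illumina comparison called 0 genes, and few simulated changes were recovered in its design. Its fibroblast and endothelial score was lower in tumor (1.80) than in breast Treg (3.77). On Ion Torrent that score was higher in tumor (4.42) than in CD45RO blood Treg (-0.58).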
